A study of Mus musculus with 6 samples.

How the data were processed

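The study measured messenger RNA in 6 libraries of mouse dermal fibroblasts, 1 for each of 2 genotypes and 3 sterols, at 100 nM for 24 h in 0.1% ethanol and 10% charcoal-stripped serum, from at least 200 ng of RNA. Cells of different mice were pooled, per the labels' protocols. Samples were grouped by the genotype and treatment given in the labels. The series' design text names other sterols and a comparison of ethanol-treated cells, and the labels of the samples were followed here. The genotypes are as labelled and were not established from the values, and a planned check of these labels is not reported here.

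The deposited values are FPKM per gene, per the file header, in 1 table of 46958 rows. Per the submitters' processing notes, STAR 2.5.4b, Cufflinks 2.2.1, Cuffdiff and the genome build GRCm38 were named. The annotation, the strand setting, the treatment of reads that fit several places and any filter are not given in the sources used here. Of the rows, 1061 merge several symbols that overlap, and 173 carry a repeated symbol. A merged row that holds a short RNA can reach a high FPKM from few fragments, so merged rows are printed with both names and stay out of the gene lists. Without a stated strand, a gene and its antisense partner cannot be told apart, and members of multigene families and genes with pseudogene copies are uncertain. Gapdh, for which many pseudogenes are known, read 5.73 FPKM in wild type, and the reason was not tested. Coordinates and transcript lengths came from GENCODE M21 on GRCm38, which located 43830 of 45897 single-symbol rows.

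Depth is not stated, so it was estimated from low values. For transcripts of 900 to 4000 nt, 97.1% to 98.3% of the low values per library were whole multiples of the value of 1 fragment within 0.05, against 10% by chance, at an estimated 7700000 to 13200000 fragments. In the results given here these fragments describe depth only.

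From the deposited FPKM, log2(FPKM + 1) was computed, and rows with a mean of at least 1 FPKM were kept (12673 rows). Fold changes are on this scale, which understates those of low genes. limma 3.58.1 in R 4.3.3 fitted genotype and sterol as additive terms over all 6 libraries, with an intensity trend in the prior variance, 2-sided tests and Benjamini-Hochberg adjustment at 0.05. The fit had 2 residual and 3 prior degrees of freedom. The interaction of genotype and sterol has no replicate and was given as values only.

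The design, the alternatives, the rule for named genes and 47 gene lists were fixed before the data were examined. The rule took the 12 higher and 12 lower genes with the largest change among those past the threshold, with a mean of at least 5 FPKM and the same sign in all 3 sterols, leaving out predicted loci. For each sterol contrast it took the 5 higher and 5 lower, or the 5 with the smallest p where fewer than 3 passed. Up to 4 members were named per list, and other members named in the text were chosen after their values were seen. The 38 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01. Camera at an estimated correlation and fry were run beside it, and all were adjusted over the lists of each contrast. At an estimated correlation camera has only the 2 residual degrees of freedom and little power, so a miss does not show an unchanged list.

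The alternatives were another pseudocount, other filters, median-of-ratios and quantile scaling, no trend or a robust prior, no sterol or genotype term, and leaving out each library or sterol. Those chosen after seeing the data were single-gene rows of at least 300 nt, protein-coding rows, removal of each library's length trend, the knockout-labelled 20(OH)7DHC library alone against wild type, and lists with merged rows added. The fit was tested on simulated data in 20 runs with 200 changed genes among 12673 and the hypoxia list also shifted. For the genotype difference it recovered 16.2%, 93.7%, 99% and 99.8% of genes changed 2-, 4-, 8- and 16-fold, with a mean of 15.5 false calls. For 20(OH)L3 against 20(OH)7DHC it recovered 5.7%, 81.5%, 97.9% and 99.4%, with 15.1 false calls. The changed genes were drawn from intermediate expression levels, and the noise was independent between genes with equal spread in all libraries. No length trend and no outlying library were simulated, so these rates may not hold for the real data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the table and the figures.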

Results

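RNA sequencing was used to profile dermal fibroblasts from the skin of newborn mice, pooled from several animals and used at early passage. The labels give a wild type (RORγ+/+) and a knockout (RORγ-/-) of the nuclear receptor RORγ. Cells of each genotype received 100 nM of 1 of 3 hydroxylated sterols for 24 h. The sterols were 20(OH)L3, a derivative of lumisterol, 20(OH)Cholesterol, and 20(OH)7DHC, a derivative of 7-dehydrocholesterol. The 6 libraries therefore hold 1 library for each genotype and sterol, and no ethanol-treated library was analysed here. The values are FPKM, which scale fragments by transcript length and by library size. Low values fell on whole multiples of the value of 1 fragment, and this gave an estimated depth of 12500000, 13000000 and 13100000 fragments for wild type with 20(OH)L3, 20(OH)Cholesterol and 20(OH)7DHC. The libraries labelled knockout held an estimated 9100000, 7700000 and 13200000 in the same order. At these depths 1 fragment on a transcript of 1 kb was worth 0.093 to 0.162 FPKM.

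Genotype separated the libraries more than sterol did. Correlations of log2 values across genes, which are not independent replicates, were 0.944 to 0.950 within wild type, 0.884 to 0.934 within the libraries labelled knockout and 0.82 to 0.87 between the genotypes. The first principal component held 55.6% of the variance and the second 17.9%. The library labelled knockout with 20(OH)7DHC stood apart from the other libraries of that label, with a score of 19.5 against 83.9 and 66.4 on the first component and 74.5 against -27.1 and -15.1 on the second. Wild type lay between -59.4 and -53.1 on the first. Short transcripts had raised values in 2 of the libraries labelled knockout. For protein-coding genes under 1 kb, the median log2 ratio of knockout-labelled over wild type was 1.23 with 20(OH)L3 and 1.02 with 20(OH)Cholesterol, against 0.03 with 20(OH)7DHC. For genes of 6 kb and over it was -0.37, -0.39 and 0.02.

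**Figure D1:**
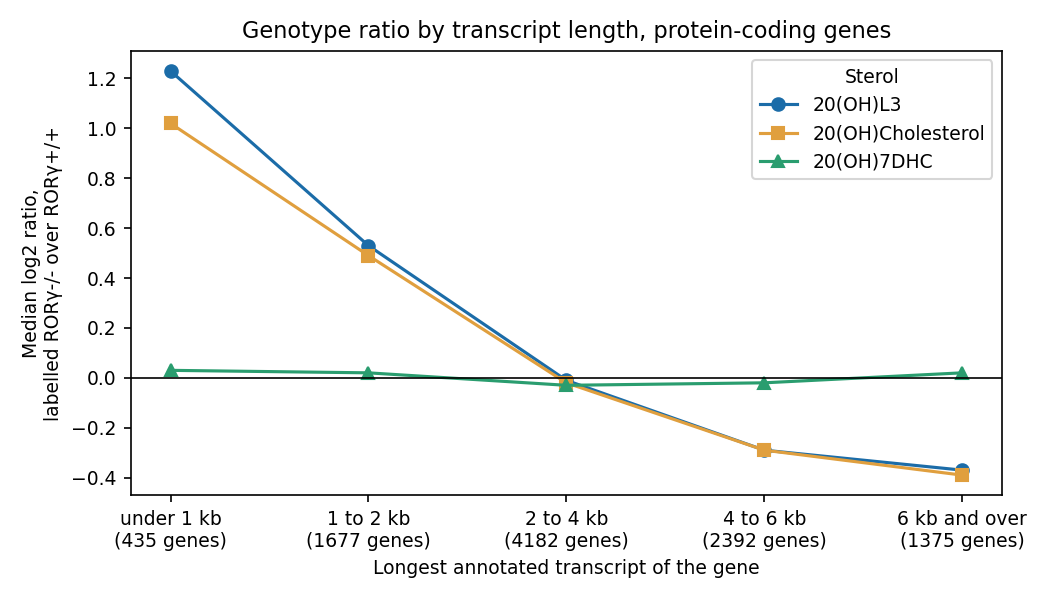
Median log2 ratio of FPKM + 1, libraries labelled knockout over wild type, by transcript length class for protein-coding genes, with 1 line per sterol. The 20(OH)L3 and 20(OH)Cholesterol lines run from 1.23 and 1.02 under 1 kb to -0.37 and -0.39 at 6 kb and over, and the 20(OH)7DHC line stays between -0.03 and 0.03.

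Every direction below is that of the libraries labelled knockout against wild type, with the genotypes as labelled. Y-linked transcripts differed between the labelled genotypes in each sterol. Eif2s3y had 35.0, 31.3 and 26.9 FPKM in wild type with 20(OH)L3, 20(OH)Cholesterol and 20(OH)7DHC, and 1.41, 0 and 0 in the libraries labelled knockout.

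**Figure D2:**
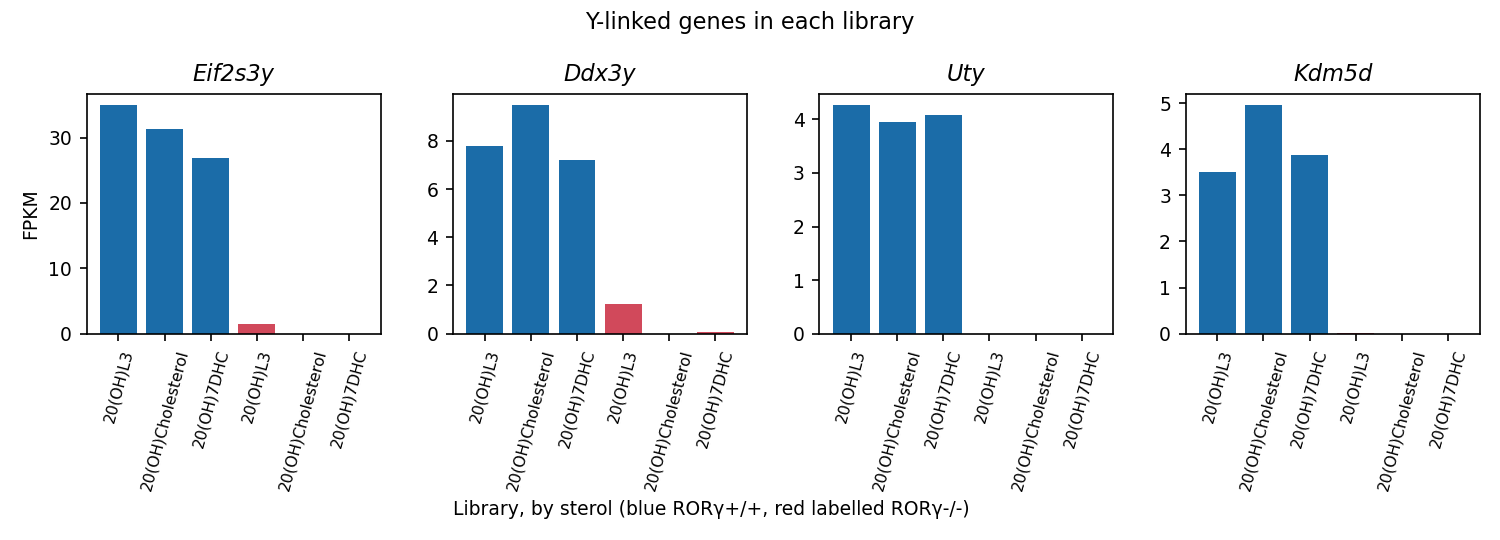
FPKM of the Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d, with 1 bar per library, wild type in blue and the libraries labelled knockout in red. Eif2s3y lies between 26.9 and 35.0 in wild type and at or under 1.41 in the libraries labelled knockout, and Kdm5d between 3.51 and 4.96 in wild type and at or under 0.0141 in the others.

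The comparison of genotypes asked which transcripts differed between RORγ+/+ fibroblasts and those labelled RORγ-/- under the same sterols. Genes of inflammation, interferon response, cell division and the extracellular matrix were lower in the libraries labelled knockout, while contractile and adipocyte genes were higher. As lists these were called by camera with the preset correlation, and none held with an estimated correlation (adjusted p = 0.277 to 0.367). The latter test has little power at 2 residual degrees of freedom, so it cannot decide whether a list changed. The acute-phase gene Saa3 fell from 7470 ± 2610 to 27.1 ± 23.8 FPKM (SD, n = 3). Dcn, which encodes the matrix proteoglycan decorin, fell from 1300 ± 175 to 14.5 ± 7.94 FPKM (SD, n = 3). Cadm1, which encodes a cell adhesion molecule, rose from 0.326 ± 0.0809 to 17.7 ± 7.77 FPKM (SD, n = 3). By limma, 1150 of 12673 rows passed an adjusted p of 0.05, 308 higher and 842 lower, and all 1150 had the same sign with each sterol. Equal signs add little, because a call already needs a difference that is large against its spread over the sterols. The calls were 576 higher and 842 lower after quantile normalization, and among single-gene rows 879 higher and 1268 lower before each library's length trend was removed and 1309 higher and 1165 lower after, alternatives chosen after seeing the data. The balance also turned with single libraries, with 1440 higher and 1124 lower without the knockout-labelled 20(OH)7DHC library, 1380 higher and 1032 lower without wild type with 20(OH)7DHC, and 6 higher and 89 lower without the knockout-labelled 20(OH)Cholesterol library. Without the wild-type 20(OH)Cholesterol library or the wild-type or knockout-labelled 20(OH)L3 library, 8, 12 and 12 were higher and 107, 186 and 198 lower. Of the 972 that were single protein-coding genes, 242 were higher and 730 lower. The 4 Y-linked genes measured also fell, so the genotype groups differed in their Y-linked transcripts as well.

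The 12 lower genes with the largest changes were mostly secreted or antiviral factors. Cxcl10 (chromosome 5, 92346638 to 92348889), a chemokine induced by interferon, fell from 305 ± 45.3 to 1.04 ± 1.37 FPKM (log2 -7.43, SE 0.453, limma adjusted p = 0.00261). Cxcl5, a chemokine for neutrophils, fell from 276 ± 34.4 to 1.16 ± 1.76 FPKM (log2 -7.29, limma adjusted p = 0.00164). Lcn2, the iron-binding protein lipocalin, fell from 227 ± 92.3 to 0.47 ± 0.532 FPKM (log2 -7.26, limma adjusted p = 0.00122). Ccl8 fell from 161 ± 32.8 to 0.34 ± 0.0888 FPKM and Ifit3, an antiviral gene, from 119 ± 6.28 to 0.0925 ± 0.0974 FPKM. Irf7, a transcription factor of the interferon response, fell from 334 ± 53.2 to 2.56 ± 1.44 FPKM. The others were Saa3 (log2 -9.12, SE 1.003, limma adjusted p = 0.011), Oasl2 (log2 -6.68), Dcn, Ifit1, Isg15 (log2 -6.21) and Ndufa4l2 (log2 -6.09).

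The 12 higher genes were more mixed. Cadm1 (chromosome 9, 47530173 to 47857637) had an SE of 0.341 and a limma adjusted p of 0.00696. S100a7a rose from 4.56 ± 6.2 to 54.1 ± 36.2 FPKM (log2 3.68, limma adjusted p = 0.0108), and Uts2b from 2.6 ± 0.373 to 56.8 ± 58.2 FPKM (log2 3.50, limma adjusted p = 0.0329). The nuclear noncoding RNA Malat1 rose from 65.4 ± 12.3 to 696 ± 484 FPKM (log2 3.02, limma adjusted p = 0.0276). Fabp4, a fatty acid carrier of adipocytes, rose from 2.33 ± 0.937 to 24.4 ± 10.9 FPKM (log2 2.87, limma adjusted p = 0.0219). Tnnt2, Lce1f, Lce1h and Erdr1 also rose, by 2.94, 2.94, 2.88 and 3.22 on the log2 scale. Hist1h2al, of the multigene histone family and annotated as a processed pseudogene of 339 nt, was listed at 0 in all 3 wild-type libraries. It had a mean of 25.7 FPKM in the others. Larp1b rose by 3.04, in a table where its symbol is repeated. The row that merges Col7a1 with the microRNA Mir711 rose by 3.97, and its value cannot be assigned to either gene.

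**Figure D3:**
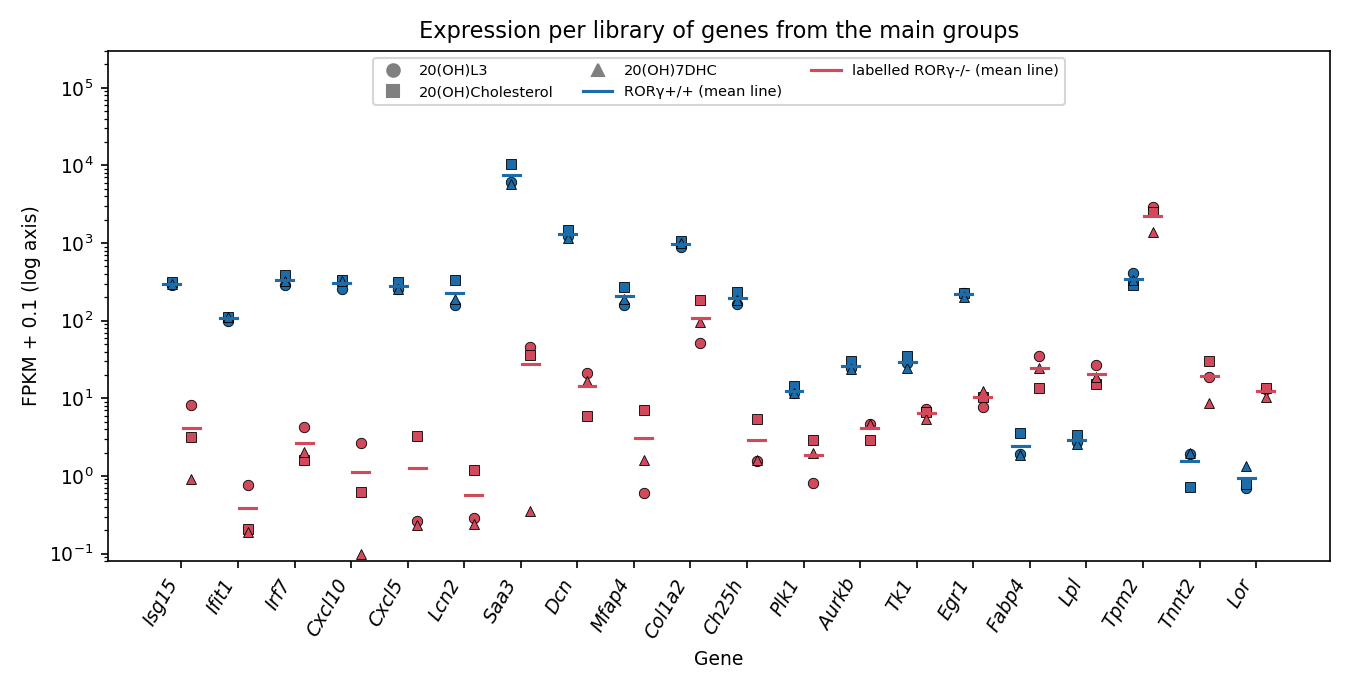
FPKM + 0.1 on a log axis of 20 genes from the lists and the ranking, with 1 point per library, a line at each genotype's mean, wild type in blue and the libraries labelled knockout in red. Saa3, Cxcl10 and Dcn have means of 7470, 305 and 1300 FPKM in wild type and of 27.1, 1.04 and 14.5 FPKM in the libraries labelled knockout.

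Interferon and inflammatory genes were lower as groups. Of 25 measured interferon response genes, 24 fell and none rose, with a median log2 difference of -4.04. Ifi35 (log2 -1.40, limma adjusted p = 0.0579) did not pass, and adjusted over the list alone all 25 fell. The camera adjusted p was 7.94e-23 with the preset correlation, and the adjusted p = 0.277 with an estimated correlation. Of 28 chemokine, cytokine and NF-kB target genes, 19 fell and 1 rose, and adjusted over the list alone 24 fell and 1 rose. Ccl2 fell from 3970 ± 35.7 to 242 ± 359 FPKM and Il6 from 55.5 ± 8.22 to 7.04 ± 3.75 FPKM, while the cytokine Il11 rose from 4.9 ± 0.18 to 37.5 ± 18.7 FPKM (SD, n = 3). This list had a median of -3.35, a camera adjusted p of 1.81e-14 and an adjusted p = 0.277 with an estimated correlation. Of 8 IL-17 and RORγ effector genes, Il1r1 (log2 -2.92), Il6st (log2 -2.22) and Stat3 (log2 -1.15) fell and none rose, and adjusted over the list alone 5 fell. Its camera adjusted p was 0.0218, and the adjusted p = 0.367 with an estimated correlation.

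Matrix genes were lower as well. Of 33 matrix glycoproteins, proteoglycans and crosslinking enzymes, 15 fell and none rose, and adjusted over the list alone 21 fell. Mfap4, a microfibril protein, fell from 207 ± 56.7 to 2.96 ± 3.42 FPKM, Lum from 13.4 ± 5.11 to 0.0362 ± 0.0345 FPKM and Postn from 418 ± 70.5 to 61.0 ± 12.9 FPKM (SD, n = 3). The matrix list had a median of -1.20 and a camera adjusted p of 1.14e-08, and the adjusted p = 0.367 with an estimated correlation. Of 18 collagen genes, 7 fell and none rose, and 8 fell when adjusted over the list alone. Col1a2 fell from 977 ± 91.2 to 110 ± 66.6 FPKM, Col1a1 from 1310 ± 170 to 414 ± 148 FPKM and Col6a2 from 28.4 ± 5.73 to 1.18 ± 0.447 FPKM. The collagen list had a camera adjusted p of 0.00154 and an adjusted p = 0.302 with an estimated correlation. Of 21 matrix metalloproteinases and inhibitors, 9 fell and none rose, and adjusted over the list alone 12 fell and 1 rose. Mmp3 fell by 4.63 on the log2 scale and Mmp9 fell by 3.85. Its camera adjusted p was 3.46e-05, with an adjusted p = 0.277 with an estimated correlation.

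Genes of the cell cycle were lower. The series' design text names cell-cycle and BRCA1 pathways for ethanol-treated cells that were not analysed here, and the lists on these subjects were fixed with that text at hand. Of 29 mitosis and G2/M genes, 23 fell and none rose, and adjusted over the list alone 28 fell. Aurkb, a mitotic kinase, fell from 26.2 ± 3.59 to 3.99 ± 1.06 FPKM, and Plk1, another, from 12.5 ± 1.56 to 1.79 ± 1.04 FPKM (SD, n = 3). The list had a median of -1.72, a camera adjusted p of 2.09e-14, and the adjusted p = 0.277 with an estimated correlation. Of 29 DNA replication genes, 15 fell and none rose, and 21 fell when adjusted over the list alone. Tk1 fell from 29.0 ± 5.23 to 6.33 ± 0.957 FPKM and the helicase subunit Mcm5 from 19.7 ± 1.23 to 5.55 ± 0.253 FPKM. Replication genes had a median of -1.15 and a camera adjusted p of 4.62e-09, and the adjusted p = 0.302 with an estimated correlation. Of 17 BRCA1 and DNA damage repair genes, 7 fell and none rose, among them the helicase gene Blm (log2 -1.64) and Brca2, and adjusted over the list alone 10 fell. Repair genes had a camera adjusted p of 4.1e-05, and the adjusted p = 0.277 with an estimated correlation. Of 20 p53 and senescence genes, 4 fell, including Btg2 (log2 -2.35) and Fas (log2 -2.79), over all genes and adjusted over the list alone, and the list was not called (camera adjusted p = 0.0876).

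Stress and signalling genes fell in part. Of 20 immediate early genes, 11 fell and 1 rose, and adjusted over the list alone 16 fell and 1 rose. Egr1 fell from 219 ± 14.6 to 10.1 ± 2.42 FPKM and Fos from 238 ± 92.5 to 13.7 ± 5.25 FPKM, while the heat shock gene Hspb1 rose from 75.6 ± 1.15 to 267 ± 82.4 FPKM (SD, n = 3). Immediate early genes had a median of -1.81 and a camera adjusted p of 6.12e-07, and the adjusted p = 0.367 with an estimated correlation. Of 22 hypoxia and glycolysis genes, 10 fell and none rose, and adjusted over the list alone 12 fell. Adm, which encodes adrenomedullin, fell by 3.62 on the log2 scale. This list had a camera adjusted p of 5.54e-06, and the adjusted p = 0.277 with an estimated correlation. Gapdh, a member of this list, read only 5.73 ± 0.134 FPKM in wild type, against 886 ± 44.2 FPKM for the glycolytic gene Eno1, and the reason was not tested, so its row may not measure that transcript well. Of 16 circadian clock and ROR genes, Nr1d1, Nr1d2, Bhlhe40 and Dbp fell and Arntl rose, and adjusted over the list alone 6 fell and 1 rose. Nr1d1, a clock repressor, fell from 28.3 ± 0.171 to 10.2 ± 0.835 FPKM, and Arntl, the clock activator, rose from 10.4 ± 0.136 to 23 ± 6.16 FPKM (log2 1.04, limma adjusted p = 0.0499). The clock list had a camera adjusted p of 0.0218 and an adjusted p = 0.368 with an estimated correlation. It was not called after quantile normalization (0.0629) or without wild type with 20(OH)Cholesterol (0.0791).

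Contractile and adipocyte genes were higher. Of 17 myofibroblast and contractile genes, 4 rose and none fell, and adjusted over the list alone 10 rose. Tpm2, a tropomyosin, rose from 343 ± 62.5 to 2260 ± 779 FPKM, and Cnn2, Cald1 and Lmod1 also rose. Acta2, the smooth muscle actin, had 2500 ± 291 FPKM in wild type and 8010 ± 970 in the libraries labelled knockout, but did not pass (limma adjusted p = 0.0644). Contractile genes had a median of 1.00 and a camera adjusted p of 2.71e-05, and the adjusted p = 0.367 with an estimated correlation. Of 7 adipocyte markers, Fabp4, Pparg, Lpl and Pnpla2 rose and none fell, and adjusted over the list alone 5 rose and 1 fell. Lpl, a lipoprotein lipase, rose from 2.77 ± 0.435 to 20.2 ± 5.73 FPKM (SD, n = 3). The camera adjusted p was 0.0218, and the adjusted p = 0.367 with an estimated correlation. Without the 20(OH)7DHC library of wild type or of the knockout label it was 0.128 or 0.129. Of 5 skeletal muscle markers only Tnnt2 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.029, and adjusted p = 0.501 with an estimated correlation). That list was not called with the length trend removed (0.0833) or without the 20(OH)L3 library of wild type (0.0515) or of the knockout label (0.0656). Of 34 cytosolic ribosomal protein genes 1 rose, Rplp0, from 659 ± 57.0 to 1770 ± 467 FPKM, and adjusted over the list alone 21 rose. The list's camera adjusted p was 1.7e-08, and the adjusted p = 0.473 with an estimated correlation. These genes are short and have many pseudogene copies. Their median ratio was 1.56, 1.23 and 0.45 with 20(OH)L3, 20(OH)Cholesterol and 20(OH)7DHC, and Rps27a read only 5.76 ± 1.51 FPKM in wild type.

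Positional genes moved both ways. Of 24 HOX genes, Hoxb5, Hoxb6, Hoxd8 and Hoxd9 rose and Hoxa9, Hoxa10 and Hoxa11 fell, and adjusted over the list alone 10 rose and 3 fell. Hoxa11 fell from 13.2 ± 2.0 to 0.731 ± 0.67 FPKM and Hoxb6 rose from 11.6 ± 1.1 to 35.6 ± 8.3 FPKM (SD, n = 3). The camera adjusted p was 0.0218, and the adjusted p = 0.367 with an estimated correlation. The HOX list was not called with the length trend removed (0.1), or without any 1 library of 20(OH)L3 (0.0587 and 0.0609) or 20(OH)7DHC (0.0629 for both). Of 18 other positional transcription factors, 6 fell and 1 rose, over all genes and adjusted over the list alone. Tbx15 rose from 10.6 ± 0.507 to 61.9 ± 26.6 FPKM (SD, n = 3), a log2 difference of 2.33. The camera adjusted p was 0.0218, and the adjusted p = 0.367 with an estimated correlation. Without the 20(OH)7DHC library of wild type or of the knockout label it was 0.0693 or 0.0778. Of 15 Wnt signalling genes, Dkk2, Dkk3 and Sfrp1 fell and Lef1 rose, and adjusted over the list alone 4 fell and 2 rose. Sfrp1, a secreted Wnt inhibitor, fell from 28.3 ± 12.3 to 1.82 ± 1.07 FPKM. The camera adjusted p was 0.0282, and the adjusted p = 0.367 with an estimated correlation. The Wnt list was not called over single-gene rows with the length trend kept (0.0502) or removed (0.0509), or without any 1 library of 20(OH)L3 (0.0501 and 0.0705) or 20(OH)7DHC (0.0629 and 0.0602).

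Sterol-related lists were not called between the genotypes by camera, while fry called the list of oxysterol, bile acid and vitamin D metabolism and that of vitamin D receptor genes (adjusted p = 0.0295 for both). None of 21 cholesterol biosynthesis genes passed in limma, over all genes or adjusted over the list alone, and the list's median was 0.07 with a camera adjusted p of 0.543. Mvk, which encodes mevalonate kinase, had 28.0 ± 3.37 FPKM in wild type and 51.2 ± 19.5 in the libraries labelled knockout (limma adjusted p = 0.105). Of 12 genes of oxysterol, bile acid and vitamin D metabolism, Ch25h fell from 194 ± 34.7 to 2.77 ± 2.26 FPKM and Cyp7b1 fell by 2.97 on the log2 scale. That list had a camera adjusted p of 0.126. Of 11 liver X receptor targets, Lpl rose (camera adjusted p = 0.226), and of 11 fatty acid synthesis genes none passed (camera adjusted p = 0.33). Of 10 vitamin D receptor genes, Pdgfa rose and Lrp5 and Camp fell (camera adjusted p = 0.124). Cyp1b1 fell among 4 aryl hydrocarbon receptor targets, a list too small to test. Adjusted over the list alone, 2 oxysterol genes, 3 vitamin D genes, 2 liver X receptor targets and 1 aryl hydrocarbon receptor target fell, 1 vitamin D gene and 1 liver X receptor target rose, and 0 fatty acid genes passed.

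Other signalling lists were called neither by camera nor by fry. Of 18 TGF-beta genes, Eng and Inhba rose and Tgfbr2 fell (camera adjusted p = 0.406). Id4 and Smad6 rose and Gdf10, Grem1 and Gdf6 fell among 19 BMP genes (camera adjusted p = 0.0991), and Gas1 fell among 9 Hedgehog genes (camera adjusted p = 0.124). Of 17 NRF2 targets, Gsta4 rose and Nfe2l2 fell (camera adjusted p = 0.73). Ddit3, Trib3 and Phgdh rose and Ddit4 fell among 19 genes of the unfolded protein and integrated stress response (camera adjusted p = 0.216). None of 7 replication-dependent histones passed (camera adjusted p = 0.065). Adjusted over the list alone, 3 TGF-beta genes rose and 2 fell, 4 BMP genes rose and 9 fell, and 6 stress response genes rose and 3 fell. In the same way 1 Hedgehog gene fell, 1 NRF2 target rose and 1 fell, and 0 histones passed.

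Markers of fibroblast subtypes and of other cell types moved with genotype in places. Camera called none of the papillary, reticular, dermal papilla, keratinocyte, pericyte and Schwann cell lists, and fry called the papillary (adjusted p = 0.0336) and Schwann cell (adjusted p = 0.0295) lists. Of 6 papillary markers, Lef1 rose and Ntn1, Pdpn and Crabp1 fell (camera adjusted p = 0.165). Of 14 reticular and hypodermal markers, Fabp4 and Pparg rose and Dpt, Cd34 and Igf1 fell (camera adjusted p = 0.187). Lef1 rose and Rspo3 and Crabp1 fell among 5 dermal papilla markers (camera adjusted p = 0.858). Of 7 keratinocyte markers, Lor rose from 0.843 ± 0.353 to 12.2 ± 1.66 FPKM and Sfn from 5.31 ± 0.523 to 57.8 ± 51.7 FPKM (camera adjusted p = 0.065). Mcam rose and Cox4i2 fell among 6 pericyte markers (camera adjusted p = 0.643), and Fabp7 rose and Egr2 fell among 5 Schwann cell markers (camera adjusted p = 0.649). Adjusted over the list alone, 1 papillary marker rose and 3 fell, 3 reticular markers rose and 6 fell, 2 dermal papilla markers rose and 2 fell, and 2 keratinocyte markers rose and 1 fell. In the same way 1 pericyte marker rose and 3 fell, and 1 Schwann cell marker rose and 1 fell. Lists with fewer than 5 measured members were not tested. Among them Trac, of lymphocytes, and Sox9, of cartilage, rose. None of 4 macrophage markers, 2 endothelial markers, 1 melanocyte marker, 1 erythroid marker and 1 mitochondrially encoded gene passed in limma, while adjusted over the list alone 1 macrophage marker and the erythroid marker fell. The macrophage markers had a median of 0.28 and a mean of -0.01, with opposite signs. Lyz2, an abundant macrophage transcript, had 4.66 ± 1.06 FPKM in wild type. The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d all fell, and Eif2s3y had a log2 difference of -4.57 (limma adjusted p = 0.00286).

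**Figure D4:**
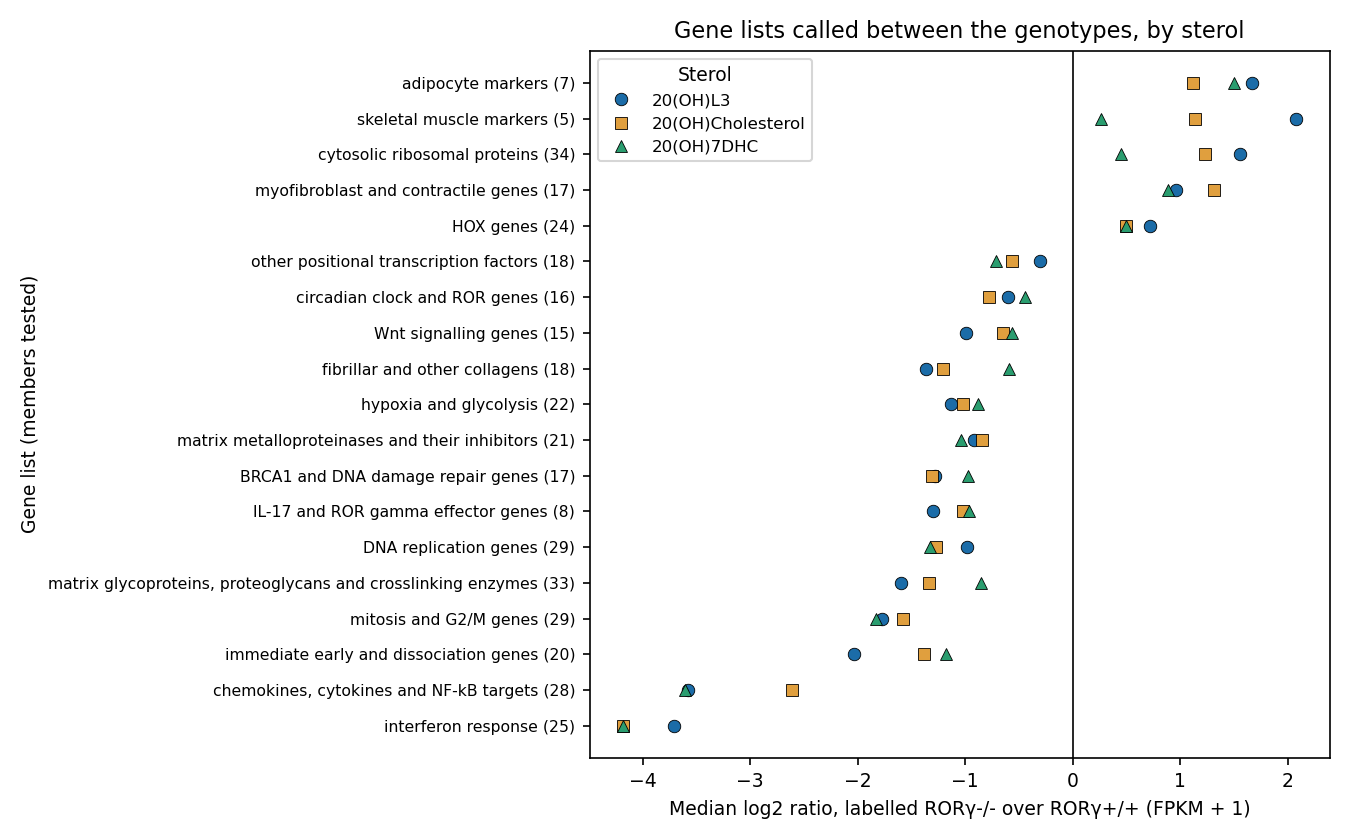
Median log2 ratio of FPKM + 1 over the members of each gene list called between the genotypes, libraries labelled knockout over wild type, with 1 point per sterol. Interferon response genes lie at -3.71, -4.18 and -4.18 and cytosolic ribosomal proteins at 1.56, 1.23 and 0.45 for 20(OH)L3, 20(OH)Cholesterol and 20(OH)7DHC.

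In all, 19 of 38 tested lists were called between the genotypes with the preset correlation, 5 higher and 14 lower, 0 with an estimated correlation and 20 by fry, which left out the HOX, skeletal muscle and ribosomal lists (adjusted p = 0.0907, 0.189 and 0.121), with 21 at an unadjusted camera p under 0.05. The number of genes depended on the sterol pairs in the fit. It was 198, 115 or 2412 without wild type with 20(OH)L3, 20(OH)Cholesterol or 20(OH)7DHC. It was 210, 95 or 2564 without the library labelled knockout with the same sterol, which breaks the same pair. The limma p-values rest on the spread of the genotype difference over the 3 sterols, combined with a prior drawn from all genes. That spread may be technical only, because the labels do not say that the cells of each library came from separate pools. Camera at the preset correlation compares the statistics of a list's genes with those of the other genes. Its p-values therefore do not measure how a list varies between libraries.

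The comparisons of sterols asked whether fibroblasts responded differently to related molecules at the same dose and time. No protein-coding gene passed limma in any of the 3 comparisons, with 482, 221 and 242 rows at an unadjusted p under 0.05. Each contrast set 2 libraries against 2, with genotype in the model. For 7451 protein-coding genes with a mean of at least 5 FPKM the 95% interval reached a median of 0.72 on the log2 scale to either side. The interval lay within a 4-fold difference for 93.7% of them between 20(OH)L3 and 20(OH)7DHC, 95% between 20(OH)Cholesterol and 20(OH)7DHC, and 97.8% between 20(OH)L3 and 20(OH)Cholesterol. It lay within a 2-fold difference for 47.7%, 50.9% and 59.2%, so smaller differences stayed open for many genes.

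20(OH)L3 and 20(OH)7DHC are derived from stereoisomers. Ccdc28b had 13.4 and 35.3 FPKM with 20(OH)L3 and 3.8 and 7.85 FPKM with 20(OH)7DHC, wild type given before knockout-labelled, a log2 difference of 1.81 (95% interval 1.08 to 2.55) that did not pass (limma adjusted p = 0.701). The antisense RNA Hoxb5os, which overlaps other transcripts, differed by -2.04 (95% interval -2.75 to -1.34, limma adjusted p = 0.663). Gga3 differed by -1.75, Nckipsd by -1.63 and Arhgap21 by -1.17, each with a limma adjusted p of 0.701. The 5 rows that passed were the short RNAs Gm26457, Gm25357, Mir6944, Snord83b and Mir7027, all lower with 20(OH)L3 and listed at 0 in both of its libraries. Mir6944 had 46.3 and 45.8 FPKM with 20(OH)7DHC, and values of this kind on so short a transcript come from very few fragments. By camera, collagen (median -0.36), matrix (-0.34) and Hedgehog (-0.47) lists were lower with 20(OH)L3 and ribosomal (0.65) and skeletal muscle (0.69) lists higher. None of the 5 held with an estimated correlation (adjusted p = 0.98) or by fry, and the ribosomal shift goes with the raised short transcripts of the knockout-labelled library. With 20(OH)L3 the median genotype ratio was -1.36 for collagen, -1.6 for matrix, -0.74 for Hedgehog and 2.08 for skeletal muscle genes. With 20(OH)7DHC it was -0.59, -0.85, 0.24 and 0.26, so these sterol differences were not equal between the genotypes.

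20(OH)Cholesterol lacks a ring double bond that 20(OH)7DHC has. Axin1, a scaffold of Wnt signalling, had 15.1 and 11.3 FPKM with 20(OH)Cholesterol and 30.9 and 32.2 FPKM with 20(OH)7DHC, a log2 difference of -1.21 (95% interval -1.81 to -0.61) that did not pass (limma adjusted p = 0.83). Cox7a1 differed by 1.85, Gga3 by -1.55 and Arhgap21 by -1.07, with the same adjusted p. Of the 5 rows that passed, Gm26457, Gm25357, Mir6944 and Mir7027 were lower and n-R5s197 higher, again short RNAs, and each was listed at 0 in both libraries of 1 sterol. By camera, chemokine (median 0.59, adjusted p = 0.000318), ribosomal (0.44), mitosis (0.26) and histone (0.55) lists were higher with 20(OH)Cholesterol and the BMP list lower (-0.31). Ribosomal and histone transcripts are short, and short genes were raised in the knockout-labelled library with 20(OH)Cholesterol (1.02 under 1 kb) and not in that with 20(OH)7DHC (0.03). None of the 5 held with an estimated correlation (adjusted p = 0.951) or by fry. The median genotype ratio was -2.61 for chemokine and -0.85 for BMP genes with 20(OH)Cholesterol, against -3.61 and -0.36 with 20(OH)7DHC. These sterol differences were therefore not equal between the genotypes. Ccl2 had 4000 and 3930 FPKM with these sterols in wild type and 657 and 17.1 FPKM in the knockout-labelled libraries, while Lcn2 was higher with 20(OH)Cholesterol in both genotypes.

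Between 20(OH)L3 and 20(OH)Cholesterol limma called 0 rows, with 242 at an unadjusted p under 0.05. Hoxb5os differed by -2.46 (95% interval -3.17 to -1.76, limma adjusted p = 0.626) and Ccdc28b by 1.38 (95% interval 0.64 to 2.11, limma adjusted p = 1). By camera, 6 lists were lower with 20(OH)L3. They were collagens (median -0.42), cholesterol biosynthesis (-0.33, adjusted p = 0.000812), chemokines (-0.46), matrix glycoproteins (-0.22), metalloproteinases (-0.16) and other positional factors (-0.27). None of the 6 held with an estimated correlation (adjusted p = 0.828) or by fry. The median genotype ratio was -3.58 for chemokine and -0.41 for cholesterol biosynthesis genes with 20(OH)L3, against -2.61 and 0.42 with 20(OH)Cholesterol. The differences of these lists were therefore not equal between the genotypes. Sqle, which encodes squalene epoxidase and was chosen after its values were seen, differed by -0.26 between these sterols (95% interval -1.02 to 0.50).

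Whether a genotype difference depended on the sterol could not be tested, because each genotype and sterol had 1 library. The median log2 ratio of the interferon list was -3.71 with 20(OH)L3, -4.18 with 20(OH)Cholesterol and -4.18 with 20(OH)7DHC, and that of the chemokine list -3.58, -2.61 and -3.61. The widest range among protein-coding genes, looked up after the values were seen, was that of Fxyd1 at 6.39. Ccl2, a chemokine for monocytes, had a ratio of -6.20, -2.60 and -7.76, and Fbxw7, a subunit of a ubiquitin ligase, one of 0.53, 0.26 and 5.47.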

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

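All tests in this part were chosen after the result was seen, except the count over other splits of the libraries.

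Only the genes named by rule and the gene lists were searched here. Of these, the following genes and 1 list had a genotype ratio that went up with 1 sterol and down with another by at least 0.5 on the log2 scale. Each sterol had 1 library per genotype, so the difference was not tested. The row of Celsr3 with Gm23156 had a range of 12.13 across the sterols, with -7.36 for 20(OH)L3 and 4.76 for 20(OH)7DHC. The row of Rpl23a with Snord42b had a range of 11.86, from -5.28 for 20(OH)Cholesterol to 6.57 for 20(OH)7DHC. The small RNA Rnu73b had a range of 11.51, from -10.76 for 20(OH)L3 to 0.75 for 20(OH)Cholesterol. The row of 4930470G03Rik with Mir1896 had a range of 8.80, that of Ftl1-ps2 with Gm26445 one of 8.70 and that of Epc1 with Mir1893 one of 7.87. All of these rows hold a short RNA or a pseudogene. Protein-coding genes outside the search also met the limit. Fxyd1 had 2.99 with 20(OH)L3 and -3.4 with 20(OH)Cholesterol, and Ccdc191 had -2.79 with 20(OH)L3 and 1.8 with 20(OH)7DHC. The dermal papilla markers had a median of -0.91 with 20(OH)L3 and 0.56 with 20(OH)7DHC, a range of 1.47.

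The number of genes called between the genotypes by limma was 1150 in the real split, and the highest of the other splits gave 0. The other splits mix the genotypes and leave the genotype difference in the residual spread, so their low counts were nearly set in advance. The real split was 1 of only 10 possible splits of 6 libraries into groups of 3, too few for a share under 0.05.

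Interferon response genes were lower in the libraries labelled knockout. With each library's length trend removed, the median stayed at -4.09, which argues against that trend as the whole cause. Leukocytes as the source of the RNA would bring their abundant transcripts, but the median wild-type FPKM of 18 leukocyte markers was 0.0623 against 69.6 for the interferon list, with Lyz2 at 4.66 and Tyrobp listed at 0; only Lgals3, which fibroblasts also express, was abundant at 89.8. The Y-linked genes had a median of -2.56, so the sex makeup of the pools may differ with genotype and sex and genotype cannot be told apart. Signalling from a few leukocytes, an infection or inflammation in 1 set of cultures, and the genotype itself also stay open and were not tested.

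HOX genes were called in both directions. All 7 called genes kept their direction and call with the length trend removed, for example Hoxa11 at -3.08 and Hoxd9 at 1.56, which argues against that trend as the cause for these genes, while the list itself was then not called by camera (adjusted p = 0.1). Pools from different body sites may give such a pattern, and 7 of 18 other positional transcription factors were called as well, but the site cannot be told apart from genotype here, since the labels give no site.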

How the results depend on the processing

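The tests on single-gene rows, on protein-coding rows, with the length trend removed and with the knockout-labelled 20(OH)7DHC library alone were chosen after seeing the data. The sterol pairs each wild-type library with a library labelled knockout, so the fit with sterol as a term is the paired one, and 2071 genes were called without that term. No paired analysis by replicate number was run, since each genotype and sterol has 1 library.

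The genotype count of 1150 was 267 with no filter, 2071 with no sterol term, 2147 over single-gene rows of at least 300 nt, 2327 over protein-coding rows, 2474 with the length trend removed and 2562 with the knockout-labelled 20(OH)7DHC library alone against wild type. In that last fit the knockout-labelled arm has no replicate, the spread comes from the 3 wild-type libraries, and the lone library is assumed to vary like them, so its count says nothing about stability. It was 343, 222 and 3266 without both libraries of 20(OH)L3, 20(OH)Cholesterol and 20(OH)7DHC. Leaving out 1 library takes its sterol out of the genotype difference, since the sterol term then fits the partner library exactly. Such fits gave 95 to 2564 calls with 1 residual degree of freedom. They gave 198, 115 and 2412 without wild type with 20(OH)L3, 20(OH)Cholesterol and 20(OH)7DHC, and 210, 95 and 2564 without the knockout-labelled library of the same sterol. No gene called in both fits had the opposite direction in any of them. These fits reuse libraries of the main fit, whose called genes had the same sign with each sterol, so a reversal was hardly possible. With no filter more rows are tested. The cause of the other moves was not tested. The other filters, scalings and priors gave 924 to 1418 calls. Flt4, not called at 0.07, was -0.03 without both 20(OH)7DHC libraries, and -0.03 to 0.13 without single libraries.

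The sterol counts rest on few short RNAs. Between 20(OH)L3 and 20(OH)7DHC limma called 0 with no filter, over single-gene rows, over protein-coding rows and with the length trend removed, and 0 to 21 without single libraries (21 without wild type and 13 without knockout-labelled 20(OH)L3). Between 20(OH)Cholesterol and 20(OH)7DHC it called 0 under the same settings, 3 with a pseudocount of 0.1 or a minimum of 5 FPKM, and 0 to 8 without single libraries (8 without either 20(OH)L3 library). Both counts were 0 without any 1 library of 20(OH)Cholesterol or 20(OH)7DHC. Between 20(OH)L3 and 20(OH)Cholesterol it called 1 with a pseudocount of 0.1, 2 with a robust prior and 0 to 14 without single libraries (14 without wild type and 10 without knockout-labelled 20(OH)L3). At an unadjusted p under 0.05 the full data gave 482, 221 and 242 rows.

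With an estimated correlation camera called 0 lists in all 4 contrasts, and fry called 20 between the genotypes and 0 in the sterol contrasts. At the preset correlation 21, 8, 9 and 8 lists had an unadjusted camera p under 0.05. With an estimated correlation the mitosis list, with all 29 genes lower, had an unadjusted camera p of 0.0121. That test has 2 residual degrees of freedom and little power, so its misses do not show that a list was unchanged. Called lists were 16 to 19 between the genotypes without single libraries. Between 20(OH)L3 and 20(OH)7DHC there were 2 with the length trend removed and 1 to 4 without single libraries. Between 20(OH)Cholesterol and 20(OH)7DHC there were 8 after quantile normalization and 1 to 8 without single libraries, and between 20(OH)L3 and 20(OH)Cholesterol 3 to 7. With the length trend removed, the HOX list had a camera adjusted p of 0.1, with a median of 0.47 (SD over members 1.27) against 0.45 (1.27) before, and the skeletal muscle list 0.0833, with 0.82 (1.19) against 1.11 (1.04). The mean limma statistic of all rows, with which camera compares a list, moved from -0.32 to 0.07, while that of the HOX list was 1.23 before and 1.35 after and that of the muscle list 2.98 and 3.16. The Wnt list had an adjusted p of 0.0502 over single-gene rows before the trend was removed and 0.0509 after, with a median of -0.52 (1.38) against -0.72 (1.35) over all rows. At 7700000 to 13200000 estimated fragments, genes near 1 FPKM rest on few fragments.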

Other observations

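The groups in this part were put together after the values were seen, and their counts are descriptions.

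Complement and antigen presentation genes were lower in the libraries labelled knockout. All 6 measured complement genes fell in limma, with a median log2 difference of -4.46. C3, the central complement component, fell from 319 ± 48.6 to 6.17 ± 4.75 FPKM (SD, n = 3), and the inhibitor Serping1 from 94.1 ± 16.6 to 0.876 ± 0.883 FPKM. Of 15 genes of the MHC and antigen processing, class II genes included, 13 fell, and H2-K1 went from 807 ± 124 to 60.5 ± 28.6 FPKM. Reads can be shared between the H2 genes, so their values are uncertain. All 4 interferon-inducible GTPases fell, including Irgm1 from 205 ± 14.6 to 19.2 ± 8.86 FPKM.

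Cornified envelope genes, which epidermal keratinocytes express late in differentiation, were higher. Of 9 measured, 5 rose and none fell, with a median of 2.15. Lor, Lce1f, Lce1h and Sfn rose, while Ivl had a log2 difference of -2.49 that did not pass (limma adjusted p = 0.0577).

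Y-linked transcripts separated the genotypes in these libraries. Uty had 4.27, 3.96 and 4.08 FPKM in wild type with 20(OH)L3, 20(OH)Cholesterol and 20(OH)7DHC, and was listed at 0 in the libraries labelled knockout. Eif2s3y had 35.0, 31.3 and 26.9 FPKM in wild type and 1.41, 0 and 0 in the others. The merged row that holds Xist had 755, 12.3 and 99.1 FPKM in wild type and 5250, 8790 and 1570 in the libraries labelled knockout.

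Some genes that are usually highly expressed read very low. Gapdh had 5.73 ± 0.134 FPKM in wild type and 5.53 ± 1.83 in the libraries labelled knockout, while the glycolytic genes Eno1 and Aldoa had 886 ± 44.2 and 1470 ± 19.9 FPKM in wild type. The ribosomal protein gene Rps27a had 5.76 ± 1.51 FPKM, against 659 ± 57.0 for Rplp0. The reason was not tested, and the treatment of reads that fit several places is not given in the sources used here.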
